A study of Mus musculus with 3 samples.

How the data were processed

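The series holds RNA-seq of 3 libraries of cells sorted from mouse lung, in 1 group. Per the labels' protocols, RNA was extracted with the miRNeasy micro kit with DNase treatment on the column, and libraries of total RNA were made with a stranded SMARTer kit. Total RNA libraries contain unspliced and noncoding transcripts, so counts are not counts of mature mRNA alone. Cells were sorted on a FACSAria instrument per the labels, and the marker and gate used for the sort are not given in the sources used here. The tdTomato transcript was not analysed here. Values of some single genes are not reported here, although counts and medians over lists and pairs include them.

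The authors' deposited table gives whole-number read counts per gene, not normalized, for 48709 mouse Ensembl genes, with their symbols, biotypes and coordinates. Per the submitters' processing notes, FastQC, Trimmomatic 0.38, STAR 2.6.1d, featureCounts 1.6.3 of the Subread package and DESeq2 1.18.1 were used; the notes give neither their order nor their settings. The notes list the builds hg38 and GRCh38, which are human, whereas the gene IDs are mouse. Of 48349 gene IDs shared with the mouse GRCm38 annotation of GENCODE release M21, 42754 (88.4%) had identical coordinates and 48329 overlapped, so coordinates are printed as the table gives them and were compared with GRCm38. How reads were assigned to strands is not given in the sources used here, and genes that overlap an antisense gene are uncertain. Of 6669 genes with at least 1000 counts over the libraries, 14 had the same counts in each library as another gene, as happens when reads that match several genes are counted at each of them. A library total could then exceed its number of reads.

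The columns are named as controls 1 to 3 and the titles as WT 1 to 3. Since WT is the only group in the labels, columns were assigned to WT libraries by their number. All 3 count columns were used. The deposited table holds no fold changes or p-values, so no comparison made by the authors is described. Replicates are separate samples by title, and nothing in the labels says that they came from separate animals.

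Levels are counts per 1000000 counts of the library (CPM), on a log2 scale with a pseudocount of 1. Fold differences on this scale understate differences of low genes. The depth was 16877297 to 18896263 counts per library, and 3 counts, the limit that a count of 0 allows, equal 0.159 to 0.178 CPM. The following choices were made before the data were examined. In all, 32 gene lists with 546 symbols were fixed, among them 12 lists of cell types other than smooth muscle that a lung sort could contain, and 20 pairs of related genes. For each list, the median over members was taken in each library and averaged, and its percentile was found among 10000 random lists of the same size drawn from the 19341 genes with a mean CPM of at least 0.5. The contractile list was compared with each other cell type as a difference of medians within a library, leaving out genes that both lists hold. Genes were named by a rule, namely the 20 genes with the highest mean CPM outside mitochondrially encoded genes and ribosomal, small nuclear, small nucleolar and 7SK or 7SL RNAs, the 3 highest members and the lowest member of each list, all genes of the pairs, and the 10 genes with the widest range between libraries among those with a mean CPM of at least 10 that varied beyond counting error. Not every gene that the rule takes is printed. Other genes named in the text were chosen after their values were seen, namely Tagln and Des, and in the closing section genes of lists added later and sex-linked genes.

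List symbols were matched by name, or by Ensembl ID through a table of current names where the deposited table uses an older symbol or lists a symbol more than once; 3 symbols had no match, of which 2 are the current names of genes already in the list. Sequence shared between genes was measured as the percentage of a gene's 50-base words found in GENCODE transcripts of another gene. Exon lengths were the union of exons in the same annotation.

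With 3 libraries, an exact two-sided sign-flip permutation test cannot give a p below 0.25, so differences within libraries are given with their SD over 3 libraries and carry no test. Variation between libraries was tested per gene with a chi-square test of homogeneity given library sizes scaled by the TMM method, for genes with at least 10 counts, with Benjamini-Hochberg adjustment over 23317 genes. The spread was summarised as the common biological coefficient of variation of edgeR 4.0.16 in R 4.3.3, with an intercept alone and genes kept by its expression filter. Both steps were tested on simulated data for 3 libraries. For the chi-square test, counts had counting error alone, and 200 changed genes were taken only from genes well above the minimum count. Of genes changed by 1.5-fold, 88.1% were recovered, and of genes changed by 2-fold and 4-fold 100%. Of 202 calls, 10 were unchanged genes. This recovery does not apply to genes with few counts or to spread beyond counting error. In a separate simulation without changed genes, a coefficient of 0.2 was estimated as 0.197. Tables were handled in Python 3.11.15 with pandas 2.3.3 and NumPy 2.4.6, and plots were drawn with matplotlib 3.10.9.

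Alternatives were library sizes from TMM, from DESeq2 1.42.0 size factors, and without mitochondrially encoded and ribosomal RNA genes, a pseudocount of 0.1, counts per kilobase of exon, the mean in place of the median over members, members with a mean CPM of at least 1, other minimum counts, and each library left out in turn. Library sizes from nuclear protein-coding genes, random lists of nuclear protein-coding genes, and members with under 1% shared words were added after the data were seen, as were 9 further lists of immune and endothelial cells.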

Results

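RNA was sequenced from 3 libraries of cells sorted from mouse lung, which the labels place in 1 group, wild type (WT), with smooth muscle as the cell type. The mice carried a smooth muscle actin CreERT2 transgene, a Cre recombinase that tamoxifen switches on, and tdTomato, a red fluorescent protein. They received tamoxifen at 75 mg/kg on each of 10 days at an age of 8 weeks, and their lungs were digested and sorted 2 months later. The table held counts for 48709 genes, with library totals of 18896263, 18355813 and 16877297 for WT libraries 1, 2 and 3. Nuclear protein-coding genes took 59.5% ± 3.11 of the counts and the mitochondrial genome 11.9% ± 1.57 (SD, n = 3). Genes annotated as microRNAs took 15.1%, 12.9% and 8.36%, and library 3 had a count at 30433 genes, against 24939 and 26207 in libraries 1 and 2. The 95% Wilson intervals of these shares were at most 0.0461 percentage points wide, and 3 counts corresponded to 0.159, 0.163 and 0.178 CPM (counts per 1000000 counts of the library), both for counting error only. Gene coordinates are those of the deposited table, which overlap the mouse GRCm38 annotation for 48329 of 48349 shared genes. There was no second group to compare with, so the account below describes levels within these libraries, as the mean and SD of 3. The labels do not say whether each library came from its own mouse, and the spread may therefore be technical, at least in part.

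The first question was how transcripts of the named cell type stood against markers of other lung cells. Transcripts of the contractile apparatus of smooth muscle were detected at low to moderate levels, and lymphocyte transcripts lay above them in each of the 3 libraries. The contractile list had a median of 3.62 ± 0.17 log2(CPM + 1). Of its 20 members, 18 had a mean CPM of at least 1, 11 of at least 10 and 0 of at least 100. The lymphoid list, made of genes of T cells, B cells and natural killer cells, had a median of 7.04 ± 0.13, with 18 of 18 members at a mean CPM of at least 10 and 13 at 100 or more. Within libraries the contractile median minus the lymphoid median was -3.42 ± 0.06, which makes the lymphoid median 10.7-fold higher on the log2(CPM + 1) scale. Of the contractile genes, 17 of 20 had a lower mean CPM than the lowest lymphoid member, Klrd1, a natural killer cell receptor at 33.5 ± 14.9 CPM. Of the lymphoid genes, 15 of 18 had a higher mean CPM than Mylk, the highest contractile member. The lymphoid list was led by Ighm, the constant region of immunoglobulin M (ENSMUSG00000076617, chromosome 12, 113418558 to 113422730), at 692 ± 173 CPM, the chemokine Ccl5 at 392 ± 109 CPM and the interleukin 7 receptor Il7r at 268 ± 38.4 CPM.

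**Figure D1:**
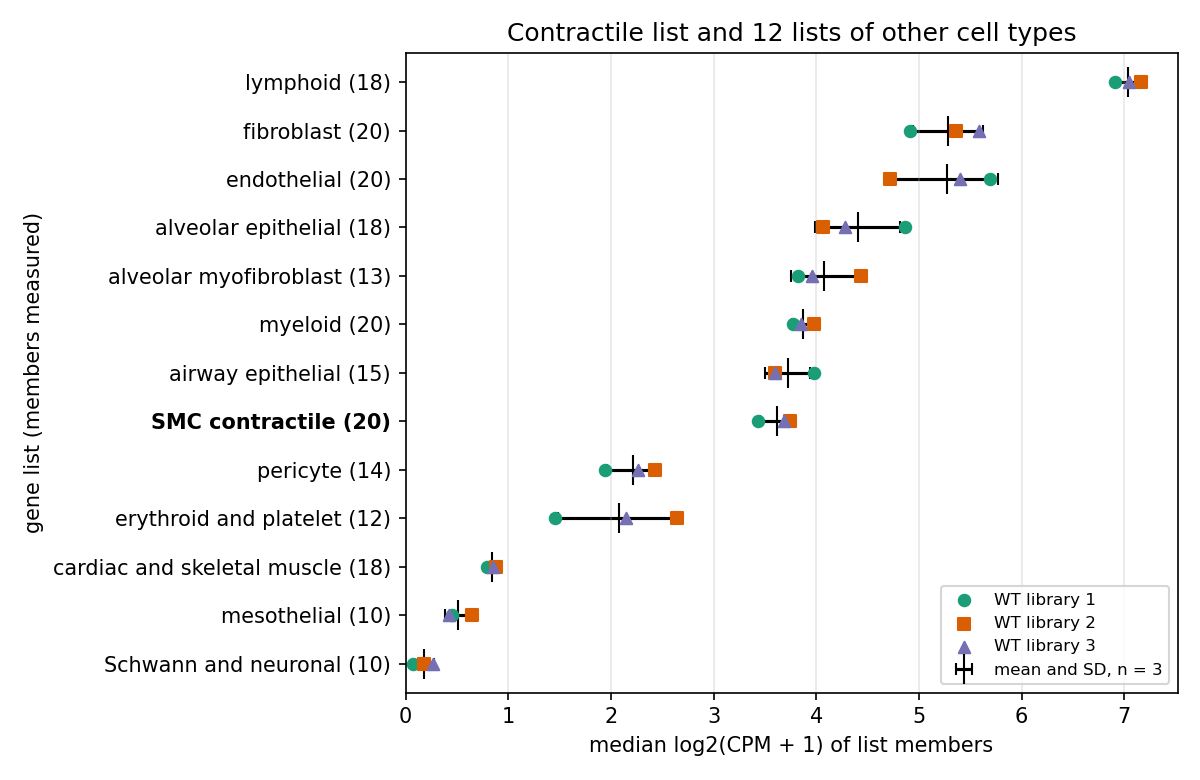
Median log2(CPM + 1) of the contractile list and of 12 lists of other cell types, with 1 symbol per WT library and the mean and SD of 3 libraries as bars. The lymphoid list lies highest at 7.04, and the contractile list lies at 3.62, between the airway epithelial and pericyte lists.

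Lists of 5 further cell types also had medians above that of the contractile list in each of the 3 libraries. The difference, contractile minus other, was -1.67 ± 0.21 for fibroblasts, -1.65 ± 0.65 for endothelium, -0.78 ± 0.58 for alveolar epithelium, -0.67 ± 0.16 for alveolar myofibroblasts and -0.25 ± 0.09 for myeloid cells. Without WT library 1 the alveolar epithelial difference was -0.46. Per kilobase of exon the alveolar myofibroblast difference was -0.068 ± 0.106, within its SD of 0, at a setting that also shrinks differences of low genes. Fibroblast genes were led by the actin-severing protein gelsolin, Gsn, at 762 ± 254 CPM, and endothelial genes by the hypoxia-inducible factor Epas1 at 456 ± 161 CPM and the adhesion molecule Pecam1 at 206 ± 29.2 CPM. In the myeloid list the leading genes were Ptprc, the CD45 phosphatase of all leukocytes (ENSMUSG00000026395, chromosome 1, 138062861 to 138175708), at 1479.6 ± 151 CPM and Cd74, the invariant chain of MHC class II, at 1019.9 ± 229.8 CPM; lymphocytes express Ptprc, and B cells express both. Ptprc ranked 16 by mean CPM among 22005 nuclear protein-coding genes. Alveolar epithelium was led by the surfactant protein genes Sftpc, Sftpa1 and Sftpb, which differed widely between libraries, and Sftpc had 1352, 246 and 284 CPM in libraries 1, 2 and 3. The myeloid difference depended on the setting: it was -0.83 ± 0.42 per kilobase of exon and -0.93 ± 0.35 with the mean over members, and 0.65 ± 0.61 once members sharing 50-base sequence words with another gene were left out.

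The airway epithelial list had a median close to that of the contractile list, with a difference of -0.10 ± 0.38 that was below 0 in 1 library and above 0 in 2. The mean difference was 0.12, -0.23 and -0.20 without WT library 1, 2 and 3. It was -0.70 ± 0.67 with the mean over members and -0.88 ± 0.67 over members with a mean CPM of at least 1. Without members sharing words it was -0.57 ± 0.55. The main difference had no common sign over the libraries, and the difference per kilobase of exon was -0.17 ± 0.61. With the mean over members and with members left out, the airway epithelial list lay above the contractile list, but by little more than 1 SD. Its median hides 1 very abundant gene, the club cell secretoglobin Scgb1a1 (ENSMUSG00000024653, chromosome 19, 9083636 to 9087958), at 13192, 2632 and 7641 CPM in the 3 libraries. Lists of 5 cell types lay below the contractile list in each of the 3 libraries. The difference was 1.41 ± 0.09 for pericytes, 1.54 ± 0.44 for red cells and platelets, 2.78 ± 0.12 for striated muscle, 3.11 ± 0.14 for mesothelium and 3.45 ± 0.10 for Schwann cells and neurons. Per kilobase of exon these fell to 0.57, 0.60, 0.92, 0.99 and 1.02, and with a pseudocount of 0.1 they were 1.62, 1.83, 3.69, 4.50 and 5.73, so the size of most depends on both settings. Of the genes in the mesothelial and Schwann lists, 4 of 10 and 2 of 10 reached a mean CPM of 1. The striated muscle list had 11 of 18 members at that level, the highest being skeletal actin, Acta1, at 8.20 ± 0.498 CPM. The red cell and platelet list was uneven. Hbb-bs, Hba-a1 and Hba-a2, globin genes that share 53.2%, 72.3% and 89.3% of their 50-base words with other genes and are therefore uncertain singly, had 531 ± 437, 441 ± 349 and 428 ± 336 CPM, whereas the platelet chemokine Ppbp had 0.0198 ± 0.0342 CPM. With the mean over members in place of the median the difference was -0.34 ± 0.54, within its SD of 0.

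**Figure D2:**
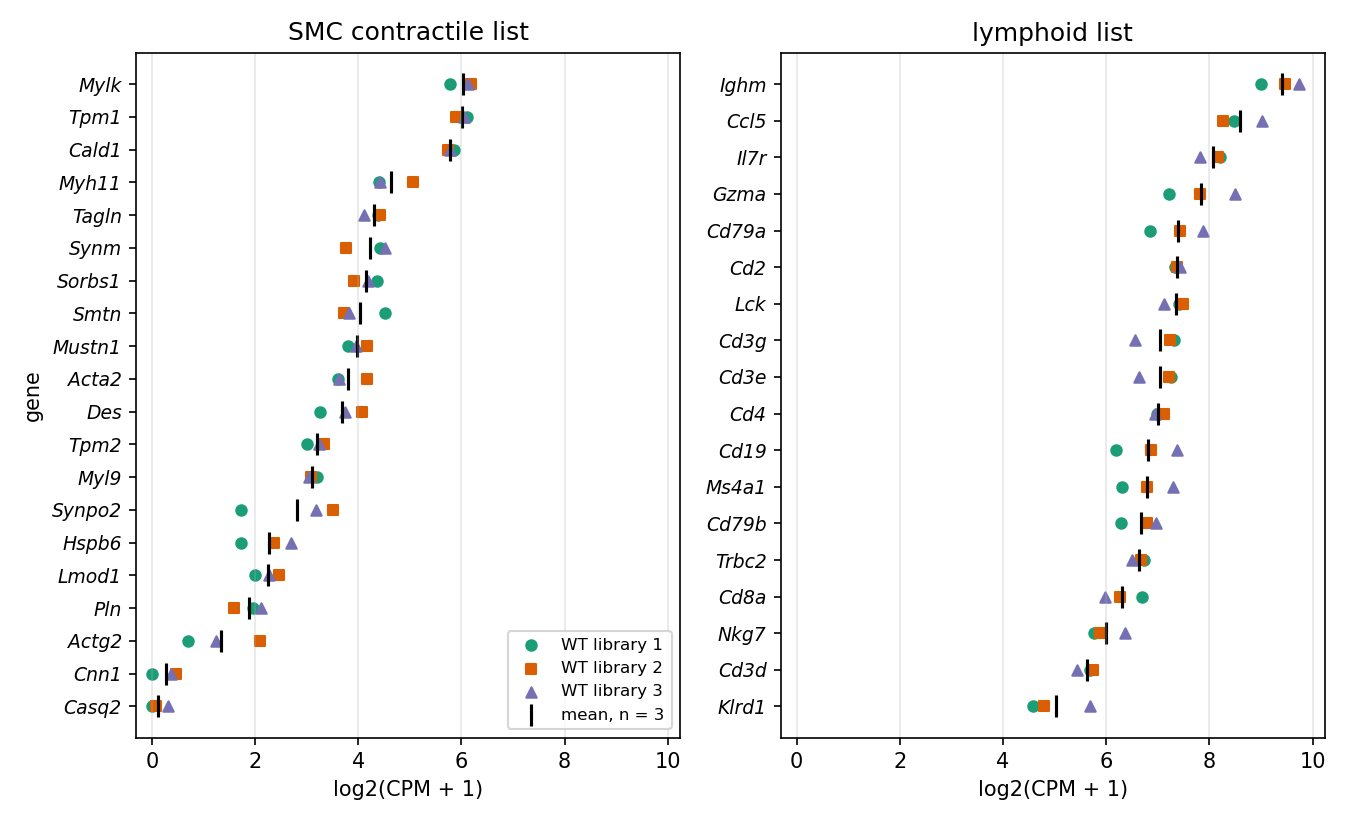
Level of each member of the contractile list (left) and of the lymphoid list (right) as log2(CPM + 1), with 1 symbol per WT library and a bar at the mean of 3. The contractile genes run from Casq2 at 0.0972 CPM to Mylk at 64.4 CPM, and the lymphoid genes from Klrd1 at 33.5 CPM to Ighm at 692 CPM.

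Within the contractile list the highest levels belonged to proteins that are also found outside muscle. Mylk, the kinase that phosphorylates myosin light chain (ENSMUSG00000022836, chromosome 16, 34745210 to 35002420), had 64.4 ± 9.57 CPM, the tropomyosin Tpm1 63.8 ± 4.94 CPM and the actin-binding caldesmon Cald1 54.1 ± 2.25 CPM. Genes used as markers of differentiated smooth muscle were lower. Smooth muscle myosin heavy chain, Myh11 (ENSMUSG00000018830, chromosome 16, 14194527 to 14291408), had 24.3 ± 6.82 CPM, and smooth muscle actin, Acta2 (ENSMUSG00000035783, chromosome 19, 34241090 to 34255336), whose promoter names the Cre transgene, had 13.2 ± 3.36 CPM. Acta2 had 211, 313 and 191 counts in the 3 libraries and ranked 7029 of 22005 nuclear protein-coding genes, inside the top 31.9%. Of these 22005 genes, only 13071 had a mean CPM of at least 1. Calponin, Cnn1 (ENSMUSG00000001349, chromosome 9, 22099281 to 22109630), had 0, 7 and 5 counts, and the 0 in library 1 allows a level of up to 0.159 CPM. Casq2, a calcium store protein, had 0, 1 and 4 counts. Tagln and Des, chosen after their values were seen, had 18.9 ± 2.30 and 12.3 ± 3.64 CPM. The median of the list lay at percentile 77.9 of random lists of the same size drawn from genes of every kind, and at percentile 47.1 of those drawn from nuclear protein-coding genes. Random lists hold only genes with a mean CPM of at least 0.5, whereas these lists keep members below it, which lowers their percentiles.

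Transcription factors that act in smooth muscle had a higher median than the contractile genes, 4.54 ± 0.33, with 12 of 20 at a mean CPM of at least 10. Klf2, Mef2d and Mef2c led at 239 ± 41.8, 199 ± 27.4 and 139 ± 50.7 CPM, and these factors are also expressed in endothelium and lymphocytes. Foxs1, a pericyte factor, had 3 counts, all in library 2. The list of vascular smooth muscle genes had a median of 2.67 ± 0.23, at percentile 26.3 of random lists, and that of airway smooth muscle genes 2.45 ± 0.18, at percentile 14.9. Among random lists of nuclear protein-coding genes these percentiles were 5.18 and 2.58. Mcam, a cell surface glycoprotein of mural and endothelial cells, had 29.5 ± 12.8 CPM, and the cGMP phosphodiesterase Pde5a had 24.9 ± 4.18 CPM. Plac9a, listed at 30.2 ± 11.3 CPM, shares all of its 50-base words with another gene and is uncertain. The olfactory receptor Olfr78 had no count in any of the 3 libraries, which allows at most 0.178 CPM in the shallowest. In the airway list the Hedgehog-binding protein Hhip (ENSMUSG00000064325, chromosome 8, 79965851 to 80058006) stood far above the other members at 351 ± 168 CPM, followed by Aldh1a1 at 61.8 ± 13.5 CPM. Hhip is also a member of the alveolar myofibroblast list, where the lysophospholipase Enpp2 followed at 99.4 ± 46.7 CPM. Pericyte genes had a median of 2.21 ± 0.25, led by the potassium channel subunits Abcc9 at 39.1 ± 17.9 CPM and Kcnj8 at 21.7 ± 4.31 CPM and by Pdgfrb at 22.4 ± 5.40 CPM.

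Paralogous genes were compared inside each library as log2 ratios, and 17 of 20 pairs had the same sign in the 3 libraries. Muscle isoforms lay below their cytoskeletal relatives. The ratio of Acta2 to cytoplasmic actin, Actb, was -7.59 ± 0.33, that of Myh11 to the nonmuscle myosin Myh9 -6.46 ± 0.33, that of Cnn1 to Cnn2 -6.90 ± 0.39 and that of Tpm2 to Tpm4 -3.94 ± 0.23. Actb itself had 2682 ± 75.9 CPM and Myh9 2176 ± 139 CPM. Among the smooth muscle actins, Acta2 exceeded the visceral form Actg2 by 2.45 ± 0.41, with Actg2 at 1.76 ± 1.36 CPM. Per kilobase of exon the ratios named so far were -6.87 ± 0.27, -4.88 ± 0.21, -4.49 ± 0.18, -3.59 ± 0.34 and 1.20 ± 0.10. With a pseudocount of 0.1 that of Cnn1, which had few counts, was -9.08 and that of Acta2 to Actg2 3.08, so both are approximate. Actb exceeded Actg1 by 2.04 ± 0.09, and Myh9 exceeded Myh10 by 4.79 ± 0.36. Notch3, the Notch receptor of vascular smooth muscle and pericytes, lay below Notch2 and Notch1, at -5.68 ± 0.35 and -4.80 ± 0.20. Its target repressor Heyl exceeded Hey2 by 2.36 ± 0.08, a ratio that depends on the 0.323 CPM of Hey2 and on the pseudocount. Per kilobase of exon the ratios of Notch3 were -3.01 ± 0.42 and -1.94 ± 0.21, and that of Heyl to Hey2 was 0.49 ± 0.18, against 4.01 with a pseudocount of 0.1. Counts per kilobase also shrink ratios of low genes, so the moves named here do not measure gene length alone.

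Among receptors, the endothelin receptor Ednra of smooth muscle lay below Ednrb, the form of capillary endothelium, at -1.21 ± 0.16, and Pdgfrb below the fibroblast receptor Pdgfra at -1.22 ± 0.22. The BMP receptor Bmpr2 exceeded Acvr2a by 2.97 ± 0.46, and Tgfbr2 exceeded Tgfbr1 by 2.56 ± 0.12. The muscarinic receptor Chrm2 exceeded Chrm3 by 1.37 ± 0.71, both at low levels of 3.60 ± 1.97 and 0.660 ± 0.265 CPM, and by 2.14 with a pseudocount of 0.1. Itpr1 lay below Itpr2 by a ratio of -0.57 ± 0.14. The 3 pairs without a common sign were Pde5a to Pde3a at 0.26 ± 0.93, Agtr1a to Agtr2 at 0.06 ± 0.18 and Col4a1 to Col1a1 at -0.01 ± 0.67. The mean ratio of the first was -0.018 without library 3, that of the second -0.016 without library 2, and that of the last 0.22 and 0.14 without library 2 and 3. Per kilobase of exon the signs of the mean ratios held, but 15 of the 20 ratios moved by more than their SD. Among them were 0.89 ± 0.31 for Bmpr2 to Acvr2a, 1.91 ± 0.11 for Tgfbr2 to Tgfbr1, 0.22 ± 0.11 for Chrm2 to Chrm3 and -0.26 ± 0.18 for Pdgfrb to Pdgfra. Exon lengths were 6053 bases for Chrm2 and 6253 for Chrm3, so length cannot account for the move of their ratio from 1.37. Counts per kilobase also shrink ratios of low genes, so these moves do not measure the effect of gene length alone.

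Programs of matrix, signalling and stress were described in the same way. Immediate early and stress genes had the highest median of the 32 lists fixed in advance, 7.28 ± 0.33, with 21 of 23 members at a mean CPM of at least 10. The AP-1 factor Junb had 881 ± 244 CPM, the zinc finger factor Egr1 520.5 ± 164 CPM and the antiproliferative gene Btg2 341 ± 76.5 CPM. Collagens followed the lymphoid list at 5.95 ± 0.55, with Col3a1 at 245 ± 128 CPM and Col1a1 at 153 ± 60.6 CPM. The basement membrane collagen Col4a1 had 142 ± 0.652 CPM. This small SD holds for scaling by library totals, whereas TMM factors were 0.951, 0.983 and 1.07 in libraries 1, 2 and 3. Elastic fibre genes lay lower, at 4.19 ± 0.37, with elastin, Eln, at 55.4 ± 26.2 CPM. Nuclear genes of oxidative phosphorylation had a median of 4.91 ± 0.10, genes of the hypoxia response 4.68 ± 0.12, growth factor receptors 4.55 ± 0.15 and the BMP and TGF-beta pathway 4.47 ± 0.16. Those lists lay at percentiles 99.1, 98.3, 98.5 and 98.1 of random lists, and at 96.1, 93.6, 94.5 and 89.1 of those of nuclear protein-coding genes. Against random lists of nuclear protein-coding genes only, the count of lists at or above percentile 95 fell from 11 to 6 of 32.

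The Wnt list, at 3.78 ± 0.30, was led by Tcf7 and Lef1, at 470.1 ± 92.9 and 253 ± 67.5 CPM, which encode transcription factors that T cells also express. The Notch list had a median of 3.24 ± 0.52, with Notch2 at 242 ± 25.5 CPM and Notch1 at 131 ± 4.72 CPM. Cyclic nucleotide signalling lay at 3.16 ± 0.18, led by Pde4b at 176 ± 14.6 CPM and Pde3b at 172 ± 29.3 CPM. Ion channels and calcium handling lay at 2.77 ± 0.24, led by the calcium release channels Itpr2 and Itpr3 and by Atp2a3, a calcium pump at 209 ± 25.6 CPM. Receptors for vasoactive and bronchoactive ligands were the lowest of the program lists at 1.34 ± 0.20, with 20 of 30 members at a mean CPM of at least 1. Of these, 8 had a mean CPM of at least 10, among them the prostaglandin receptor Ptger4 at 36.0 ± 1.58 CPM, whereas the adrenoceptor Adra1b had 0.0395 ± 0.0684 CPM. Proliferation genes had a median of 1.99 ± 0.26, although Pcna, of which 19.1% of 50-base words occur in other genes, had 90.2 ± 24.4 CPM and Mki67 47.1 ± 10.8 CPM. Medians were 2.75 ± 0.41 for inflammatory cytokines and chemokines, 3.40 ± 0.35 for senescence genes and cell cycle inhibitors, and 2.61 ± 0.16 for imprinted genes. Ccl21a led the chemokines at 94.8 ± 40.1 CPM and shares 71.6% of its 50-base words with other genes.

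Among the 20 most abundant genes outside the mitochondrial genome and the classes of small structural RNA, 6 were annotated as microRNAs. Gm23935, at 46938 ± 13742 CPM, was the highest, followed by Gm24270 and Gm24187. The class is that of the deposited table, and whether these reads came from microRNAs was not tested. Pseudogenes Gm12895 and Gm12896 had almost equal counts, as happens when reads are counted at more than 1 gene, and their levels are uncertain. The long noncoding RNA Malat1 had 10260 ± 2599 CPM. Protein-coding genes in this set included Scgb1a1, the elongation factor Eef1a1 at 3161 ± 69.1 CPM, Tpt1, Actb, the mitochondrial leucyl-tRNA synthetase Lars2, the scaffold protein Ahnak and the chaperone Hspa8. No contractile gene of smooth muscle was among them.

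The last question was how far the 3 libraries differed from one another. Counts of 16333 of 23317 genes varied by more than counting error in a chi-square test of homogeneity at a Benjamini-Hochberg adjusted threshold of 0.05. Leaving out WT library 1 took this count to 8275, leaving out library 2 to 11625 and leaving out library 3 to 12273. The common biological coefficient of variation from edgeR was 0.266, or 0.438 with no filter on low counts. Pearson's r of log2(CPM + 1) across genes was 0.961 for libraries 1 and 2, 0.968 for 1 and 3 and 0.980 for 2 and 3; genes are not independent replicates. As a check for copies of 1 library, chi-square statistics of library pairs were 41.2, 54.9 and 44.1 per degree of freedom. Such tests set separate samples against counting error alone, so they do not measure how far the libraries differ.

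Epithelial and endothelial lists stood higher, and fibroblast and collagen lists lower, in library 1 than in the others. Relative to all genes, the alveolar epithelial list in library 1 lay 1.12 above the mean of the other libraries on the log2 scale, with 14 of 18 members highest there, the airway epithelial list 1.22, with 12 of 13, and the endothelial list 0.96, with 17 of 20. In the same library the fibroblast list had a shift of -0.83 and the collagens -0.83. Other lists also stood apart there: mesothelial genes at 0.90, with 4 of 4 highest, red cell and platelet genes at -1.32, with 8 of 9 lowest, and immediate early and stress genes at -0.46, with 20 of 23 lowest. Elastic fibre, pericyte and alveolar myofibroblast lists had shifts of -0.55, -0.47 and -0.47. Among lists written later, neutrophil genes lay at 0.73 and plasma cell genes at -1.29. Library 2 was highest for the red cell and platelet list, with a shift of 1.85, and for 11 of 13 alveolar myofibroblast genes, with a shift of 0.74. The lymphoid and contractile lists moved less, with median shifts between -0.18 and 0.22 in the 3 libraries. Lymphoid members went both ways, however, with 10 of 18 highest and 8 lowest in library 3. Shifts in libraries 1, 2 and 3 were 0.25, 0.23 and -0.48 for a list of T cell genes and -0.72, 0.10 and 0.61 for 1 of B cell genes, both written after some values were seen. The median of all genes with a mean CPM of at least 1, to which these shifts are relative, had log2 ratios to the mean of the other libraries of -0.09, -0.02 and 0.13 in libraries 1, 2 and 3. These are descriptions of single libraries, which carry no test.

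**Figure D3:**
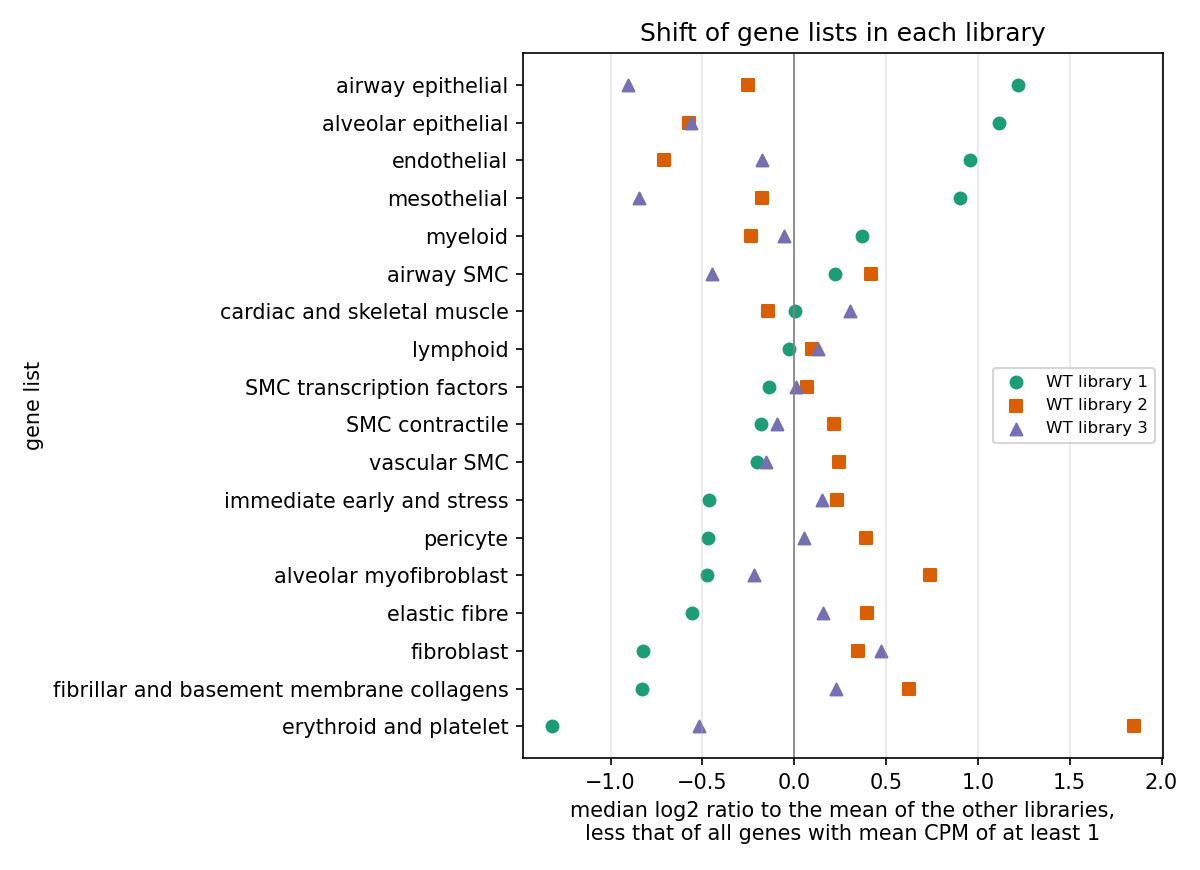
Median log2 ratio of each list in 1 library to the mean of the other libraries, less the same median over all genes with a mean CPM of at least 1, with 1 symbol per WT library. Airway and alveolar epithelial lists reach 1.22 and 1.12 in library 1, and the red cell and platelet list reaches 1.85 in library 2.

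Of the 10 genes with the widest range between libraries, 6 were variable segments of immunoglobulin genes, each highest in library 2. Ighv1-19 had 0.212, 26.6 and 5.39 CPM in libraries 1, 2 and 3, and Igkv1-110 had 10.3, 182 and 53.4 CPM. Such segments resemble one another, and their reads can be assigned to the wrong member. The other genes were Plekhh2 (ENSMUSG00000040852, chromosome 17, 84511895 to 84622142), with 7.04, 151 and 76.0 CPM, the guanylate-binding protein Gbp2b, with 24.0, 23.5 and 0.415 CPM, the protease cathepsin E, Ctse, with 129, 78.5 and 10.7 CPM, and Eps8l1, with 34.2, 2.29 and 2.84 CPM. Gbp2b had 454 and 431 counts in libraries 1 and 2 and 7 counts in library 3.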

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

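Leaving out members with shared words, nuclear protein-coding library sizes and percentiles among nuclear protein-coding genes were chosen after the data were seen. Over the 12 list differences, 103 settings stayed within 1 SD of the main value, 37 moved further with the same sign and 4 reversed. Over the gene pairs, 152 of the settings stayed within 1 SD with the same sign and 28 did not. Of these 28, 4 turned the sign of a mean ratio, by less than 1 SD: leaving out library 3 gave -0.018 for Pde5a to Pde3a and 0.14 for Col4a1 to Col1a1, and leaving out library 2 gave -0.016 for Agtr1a to Agtr2 and 0.22 for Col4a1 to Col1a1. These 3 pairs had no common sign over the libraries. TMM and DESeq2 scaling changed no sign. Leaving out 1 of 3 libraries cannot move a mean by 1 SD, and library sizes act on a difference within a library only through the pseudocount. Settings of these kinds had little room to move, so the counts of settings that stayed do not measure how stable the differences are. The lymphoid difference stayed between -3.66 and -3.26: -3.52 with a pseudocount of 0.1, -3.66 with the mean over members, -3.26 over members with a mean CPM of at least 1 and -3.51 without members sharing words.

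The 4 reversals concerned 3 lists, and the cause was not tested. The myeloid difference of -0.25 became 0.65 without members sharing words. The erythroid and platelet difference of 1.54 became -0.34 ± 0.54 with the mean over members. Over members with a mean CPM of at least 1 it became -0.32 ± 1.13, and both values are smaller than their SD. The airway epithelial difference of -0.10 ranged from -0.23 to 0.12 with 1 library left out, and was 0.12 without WT library 1. The alveolar epithelial difference of -0.78 was -0.46 without WT library 1.

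Counts per kilobase drew many differences towards 0. That setting also shrinks differences of low genes, and the share of gene length in these moves was not tested. The values were 0.57 for pericytes, -0.068 for alveolar myofibroblasts, -1.27 for fibroblasts and 0.60 for erythroid and platelet genes. They were 0.99 for mesothelial, 1.02 for Schwann and neuronal and 0.92 for striated muscle genes, but -0.83 for myeloid genes. With the mean over members the values were 0.98 for pericytes, -1.17 for alveolar myofibroblasts, -1.92 for fibroblasts, -0.70 for airway epithelium, -0.93 for myeloid, 2.54 for mesothelial, 2.90 for Schwann and neuronal and 2.36 for striated muscle genes. Over members with a mean CPM of at least 1 they were 1.04, -0.50 and -0.88 for pericytes, alveolar myofibroblasts and airway epithelium, and 2.47, 2.21 and 2.28 for mesothelial, Schwann and neuronal, and striated muscle genes. A pseudocount of 0.1 gave 1.62 for pericytes, 4.50 for mesothelial, 5.73 for Schwann and neuronal and 3.69 for striated muscle genes. Without members sharing words the values were 1.27 for pericytes, -0.57 for airway epithelium and 2.52 for erythroid and platelet genes. Nuclear protein-coding library sizes gave 3.55, 4.05 and 3.10 for mesothelial, Schwann and neuronal, and striated muscle genes, and library sizes without mitochondrial and ribosomal RNA gave 3.62 for Schwann and neuronal genes. These last 3 lists lie near the floor of detection, where the pseudocount moves the difference.

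Of the 32 lists, 11 lay at or above percentile 95, and 6 did among nuclear protein-coding genes. The count of genes varying beyond counting error ranged from 8275 to 12273 with 1 library left out, against 16333. The biological coefficient of variation of 0.266 became 0.438 with no filter on low counts and ranged from 0.206 to 0.304 with 1 library left out. Other thresholds for a comparison made by the authors, planned in advance, could not be run because the table holds no such comparison. No paired analysis was possible because there is 1 group.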

Other observations

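The tests below that were chosen only after the results were seen are those of smooth muscle RNA as the main RNA and of gene length for the lymphoid list, the latter from a value planned in advance as an alternative, and those of the amount of alveolar RNA and of scaling for library 1; the comparison of the variable segments with other genes and the test without members sharing words were also added after the data were examined.

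To see which leukocytes and endothelial cells the transcripts belong to, 9 further lists were written after some of their genes' values had been seen, and they are described without a test. T cell genes had a median of 6.82 ± 0.21 log2(CPM + 1) (SD, n = 3), with 20 of 20 members at a mean CPM of at least 10. Besides Tcf7 and Il7r they included the coreceptors Cd4 at 128 ± 7.94 CPM and Cd8a at 80.2 ± 20.9 CPM. B cell genes lay at 6.76 ± 0.46, with the B lineage factor Pax5 at 234 ± 77.3 CPM, and genes of MHC class II presentation at 6.31 ± 0.51. Natural killer and cytotoxic genes lay at 5.42 ± 0.44, with granzyme A, Gzma, at 244 ± 107 CPM and the receptor Ncr1 at 48.7 ± 18.0 CPM. Plasma cell genes lay at 4.21 ± 0.28, dendritic cell genes at 2.28 ± 0.37 and neutrophil genes at 1.42 ± 0.21. Lymphatic endothelial genes lay at 5.25, 4.30 and 4.05 in libraries 1, 2 and 3, and genes of arterial and capillary endothelium at 3.78, 3.97 and 4.18, so their order turned in library 3. The medians of the arterial and capillary list do not follow most of its members, of which 7 of 12 were highest in library 1. Relative to all genes, its median shifts were 0.77, -0.77 and 0.07 in libraries 1, 2 and 3. The lymphatic factor Prox1 had 8.40 ± 3.23 CPM.

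The immune lists differed between libraries in different ways. In library 3, 14 of 15 B cell genes, 14 of 14 natural killer genes and 12 of 12 MHC class II genes were highest, while T cell genes were highest there in 1 of 20. All genes also leaned towards library 3, with a median log2 ratio to the mean of the others of 0.13. Relative to that median, shifts were 0.61 for B cell, 0.59 for natural killer, 0.46 for MHC class II and -0.48 for T cell genes. Plasma cell genes were highest in library 2 in 11 of 13, and Igha, the constant region of immunoglobulin A, had 264, 2001 and 469.7 CPM in libraries 1, 2 and 3. Lymphatic endothelial genes were highest in library 1 in 7 of 8. Haemoglobin Hbb-bs had 228, 1033 and 332 CPM.

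The lymphoid list lay above the contractile list in libraries labelled as smooth muscle. Reads shared between near-identical genes as the whole cause are argued against by the difference of -3.51 over members without shared words, and gene length by -3.43 per kilobase of exon. Smooth muscle RNA as the main RNA is argued against by the marker ranks. The best of Acta2, Myh11, Tagln and Cnn1 stood only within the top 22.7% of all 22005 nuclear protein-coding genes. Of these genes, 13071 had a mean CPM of at least 1. RNA from T and B cells is a candidate source. Of 362 annotated variable segments of T cell receptor and immunoglobulin genes, 346 (95.6%) had at least 3 counts. The bound of 50%, set before the segments were counted but after the lymphoid levels were seen, is an easy one, since 58.8% of all genes pass 3 counts. Shares chosen later for comparison were 28.6% of 189 variable pseudogenes of the same gene families and 14.2% of 1129 olfactory receptor genes. Reads shared between similar segments can still raise the share. A gate on tdTomato or against CD45 might deplete T and B cells, but whether one was used is not given in the sources used here. A mislabelled table, free RNA and an incomplete sort stay open, and apart from RNA of other cells no biological explanation was tested, since the design has 1 group.

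Alveolar epithelial genes were highest in WT library 1. A difference in library size or scaling is argued against by the shift of 1.12 on the log2 scale relative to all genes, and gene length by a shift of 1.13 relative to the 200 genes nearest in exon length. A larger amount of alveolar epithelial RNA in library 1 stays open, whether from whole cells or as free RNA: that 77.8% of the 18 members were highest there restates the pattern and does not test it. A gate on tdTomato might deplete such cells, but whether one was used is not given in the sources used here. No biological explanation was tested, since the libraries are in 1 group.

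Some values stand outside these lists. Xist, the noncoding RNA of the inactive X chromosome, had 486, 619.5 and 845 CPM in libraries 1, 2 and 3. The Y-linked genes Ddx3y, Eif2s3y and Kdm5d had 26, 28 and 29 counts in library 1, and Ddx3y had 1 and 1 counts in libraries 2 and 3. Uty, which is also Y-linked, had 0, 12 and 3 counts in libraries 1, 2 and 3, and the labels give no sex. A count in library 3 alone was found for 4422 genes, against 1045 in library 1 alone and 1369 in library 2 alone, although library 3 had the lowest total. The long noncoding gene Gm26917 had 7603, 19759 and 4113 CPM.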
